A study of Mus musculus with 3 samples.

How the data were processed

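ZFP410, a zinc finger protein that binds DNA, was mapped by CUT&Tag in mouse brown preadipocytes, the precursor cells of thermogenic fat. In CUT&Tag an antibody tethers a transposase to chromatin, and the enzyme cuts and tags the DNA around the bound protein. The 3 libraries were 1 with a ZFP410 antibody on untreated cells, 1 with the same antibody after 3 days in brown adipocyte differentiation medium (called induced here), and 1 with control IgG on untreated cells. Groups were taken from the sample labels. Each group held 1 library, so no difference has a replicate check and no p-value is given. No paired analysis was possible for the same reason, and an IgG library of induced cells was not analysed here.

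Reads were processed with Bowtie2 2.2.6, Picard and MACS2 2.1.1 on the mouse build mm10, per the submitters' processing notes. The deposited files are MACS2 peak lists, 1 per library, and the peak names carry a q threshold of 0.1, as read from the deposited files themselves. For each peak the authors' lists give a score, the fold over the local background at the summit, the −log10 of the p-value and of the q-value, and the position of the summit. How duplicate reads were treated and which control was given to the caller are not given in the sources used here. The authors' fold and −log10 values describe a peak within its own list. They were used to rank and filter peaks within a list and were not compared between lists as a measure of change.

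MACS2 sets the fold as summit fragments plus 1 over background plus 1, and the p-value as a Poisson tail of the same pair. Both values together returned a whole number of summit fragments and a local background for 3255 of 3256 untreated, 7474 of 7475 induced and all 480 IgG peaks, with a gap under 0.001 in −log10 p. On simulated peaks the step returned the planted fragments for 99.1%, 99.9% and 96.2% of 1000, 999 and 1000 peaks with the background of the untreated, induced and IgG lists. The genome-wide background was 0.110, 0.246 and 0.0231 fragments. Local backgrounds above it fell on a grid of whole control fragments for 99.8%, 100% and 100% of the 612, 1764 and 386 values tested, within 3e-05 fragments, where 2.37%, 1.06% and 11.4% would do so by chance. The grid step, 0.202, 0.406 and 0.0288, is the depth of the library over that of its control. With the caller's default mouse genome size, which was assumed and not read from a file, the depths come to 1.62, 3.25 and 0.231 M fragments. The same assumption gives a control of 8.01 M fragments for each list, so the 3 lists appear to share a control that is deeper than any of the 3 libraries. The induced library was thus 2.01 times as deep as the untreated one, and the untreated one 7.02 times as deep as IgG.

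Enrichment at a summit was taken as fragments over the genome background of the same library. The genome background of the induced library was 2.24 times that of the untreated one, more than the 2.01 of depth. Ratios and numbers expected at equal enrichment use the 2.24. Ratios of enrichment, induced over untreated, were summarised over shared peaks whose local background was at most 2 times the genome background in both lists. For named genes and named peaks the ratio was computed whatever the local background, and Per1 and Orai2 exceeded that bound. Their 95% intervals are exact binomial intervals on the 2 fragment numbers, and shares have 95% Wilson intervals. Both cover counting error only, since fragments of 1 library say nothing of the spread between cultures. A share of 0 allows up to 3 counts of the total.

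The gene table used here, of the assembly GRCm38.p6 (the same coordinates as mm10), gives the first and last base of each gene but no strand, exon or sequence. The planned promoter window therefore became a window of 1 kb around either end of the 21887 protein-coding genes on placed chromosomes, called a gene end. Which of the ends is the transcription start was not determined, and exons, introns, UTRs and the ZFP410 motif were not analysed here. Peaks in lists overlapped when they shared at least 1 bp. Chance overlap came from 1000 shuffles of peak positions within chromosomes, and chance gene-end shares from 200. These shuffles ignore mappability and the control that the lists share. Gene lists were set against 10000 random lists of coding genes of equal size.

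Named genes followed a rule fixed before the data were examined. It took Wtap, Ptger3, Zfp410, Psmd6 and Chd4 whatever their values, the 10 genes of highest fold with a gene-end peak in the induced list alone, and the 5 of highest fold in the untreated list alone. It also took the 10 best ranked genes in both lists, up to 4 occupied members of each gene list, and the 3 IgG peaks of highest fold. Genes with an IgG peak were left out of the induced, untreated and shared choices. Predicted genes were skipped there, 38 among genes of the induced list alone, 10 of the untreated list alone and 17 of both. A gene that the rule took from the induced list alone is not reported here. The same rule was applied to peaks by position. The 19 gene lists were fixed with it, and 1 list of heat shock and chaperone genes was added after the strongest peaks had been seen.

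Alternatives were a −log10 q of at least 5, a fold of at least 5, placed chromosomes alone, other overlap rules, other windows and leaving out peaks or genes with IgG signal. Some were added after the data had been seen, namely peaks without chromosome Y, peaks of at least 100 times the genome background, and other scales and choices of sites for the enrichment ratio. Depth was equalised by drawing summit fragments at random, 100 times, down to the depth of a shallower library, and keeping summits that passed that library's lowest −log10 p. The draw ignores the caller's minimum peak width. On simulated sites, thinning a library to the depth of a shallower one returned 99.6% of the 6573 sites with 5 or more fragments seen in a separate draw at that depth. That simulation used fixed sites and no p-value threshold, so it checks the draw and not the calling of peaks. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.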

Results

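CUT&Tag peaks of ZFP410 were available for untreated brown preadipocytes and for cells kept 3 days in brown adipocyte differentiation medium, with an IgG library of untreated cells as the background. The cells had been sorted from brown fat of C57BL/6 mice. The lists held 3256 untreated, 7475 induced and 480 IgG peaks, which covered 819, 2308 and 246 kb. The median summit held 4 fragments in the untreated, 7 in the induced and 4 in the IgG list. The induced library was 2.01 times as deep as the untreated one and 14.1 times as deep as IgG, so a site of equal enrichment was more readily called in it. Each group had 1 library, and the differences that follow compare libraries, not conditions with a known spread.

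The question of where ZFP410 sat on chromatin was first put to genes chosen in advance. Chd4, which encodes the ATPase of the NuRD chromatin remodelling complex and is a ZFP410 target in other cells, had several peaks in and around it. A peak between Lpar5 and Chd4, at 125088495 to 125089395 on chromosome 6 (mm10), ranked 2 of the untreated list by the authors' fold, with 35 summit fragments. Its summit was 2879 bp from Lpar5 and 6972 bp from Chd4, outside the gene-end window of both. The overlapping induced peak, at 125087145 to 125090860, ranked 1 of its list with 227 fragments. Its enrichment over the genome background was 2.89-fold that of the untreated peak (95% interval 2.02 to 4.26). A further peak lay at the lower end of Chd4 (gene at 125095980 to 125130591). It ranked 142 of the untreated and 25 of the induced list, with 10 and 52 fragments, a ratio of 2.32 (1.17 to 5.12). Within 20 kb of Chd4 there were 13 untreated, 8 induced and 0 IgG peaks. Single induced peaks spanned stretches where several untreated ones were called.

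**Figure D1:**
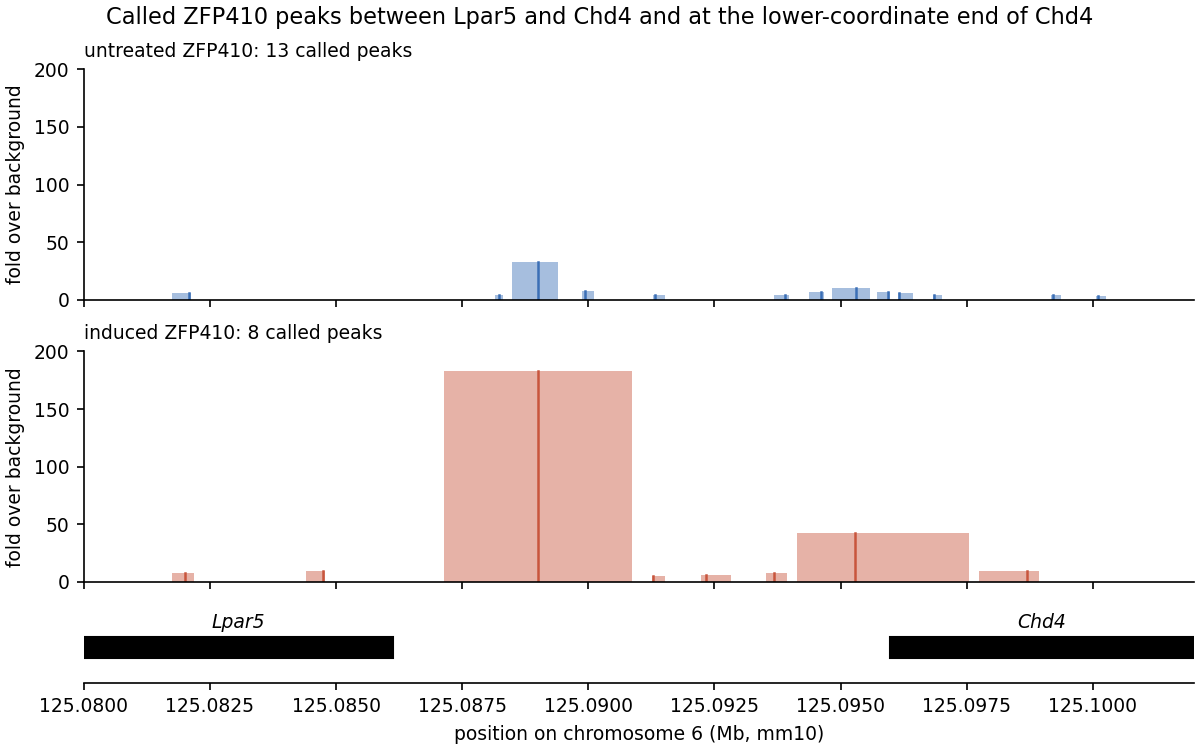
Called peaks between Lpar5 and Chd4 on chromosome 6, with the untreated list above, the induced list in the middle and the gene extents below. Boxes span each peak, their height is the authors' fold within its own list, and the line in a box is the summit; the highest box in the induced list reaches a fold of 183.

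Wtap, which encodes a subunit of the m6A RNA methyltransferase, Ptger3, which encodes the prostaglandin E2 receptor EP3, and Psmd6, a proteasome subunit gene, had no gene-end peak in either ZFP410 list. The summit nearest to an end of Wtap lay 6171 bp away in the untreated list and 6201 bp away in the induced list. These peaks, at 12960484 to 12960768 and 12960433 to 12960987 on chromosome 17, overlapped and held 3 and 7 fragments. The nearest summits to Ptger3 were 237989 and 302230 bp away, and those to Psmd6 859586 and 98980 bp away. Zfp410 itself had an induced peak of 5 fragments within 1 kb of its end and no untreated one. At equal enrichment 2.23 fragments would have been expected there in the untreated library, below the 3 of the weakest untreated peak. The absence of an untreated peak therefore says little at this depth.

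The strongest ZFP410 sites were shared by untreated and induced cells. A site inside Alg9, a gene of protein glycosylation, led the untreated list (chromosome 9, 50814711 to 50815274) with 84 fragments and held 150 in the induced library, a ratio of 0.797 (0.606 to 1.05). Gene-end sites at Prr11 and Ska2, which share a peak, and at Mrpl45 had ratios of 0.975 (0.609 to 1.60) and 0.944 (0.582 to 1.57). Stip1, encoding a cochaperone of Hsp70 and Hsp90, stood higher in the induced library at 2.58 (1.55 to 4.52). A site between genes near Gpr141 (chromosome 13, 19920328 to 19921842) had a ratio of 2.28 (1.49 to 3.62), and one near Enpp2 a ratio of 1.87 (1.15 to 3.17). Other top shared sites, inside Btbd9 and Pde1a and near Slc38a2 and Tex44, had intervals that included 1. The heat shock genes Hspa1a and Hspa1b, the transcription factor gene Zfp143, the clock gene Per1 and Orai2 also carried peaks in both lists, with ratios between 0.786 and 1.30.

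Over the full lists, 47.7% of untreated peaks overlapped an induced one (1553 of 3256, 95% interval 46.0 to 49.4), against 0.157% after shuffling. In turn 20.6% of induced peaks overlapped an untreated one (19.7 to 21.5). Overlap rose with rank, from 39.9% of untreated peaks after the top 500 to 90.8% of the top 500 and 100% of the top 50. For induced peaks the shares were 16.7% after the top 500, 74.6% of the top 500 and 98.0% of the top 50. Part of the overlap may come from the control that the lists shared. Among peaks at the genome background, where the local control added nothing, the shares were 44.0% and 20.9%. Across 1254 shared peaks of low background the median ratio was 0.818, or −0.29 on the log2 scale (quartiles −0.68 and 0.20). Scaled by relative depth in place of genome background, the median of the same peaks was 0.912, or −0.13. By genome background the interval lay above 1 at 20 of these sites and below 1 at 20, a split that depends on the scale. Set against the median ratio instead, it lay above at 54 and below at 4. That median comes from pairs called in both lists, where the lowest called numbers were 3 untreated and 4 induced fragments. Selection can therefore shift the median and the 54 and 4 with it. With 95% intervals at 1254 sites some lie off 1 by counting error alone, and no allowance was made for the number of sites. Sites chosen for their strength in one list favour that list, and the 200 induced peaks with most fragments gave 0.62 on the log2 scale.

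**Figure D2:**
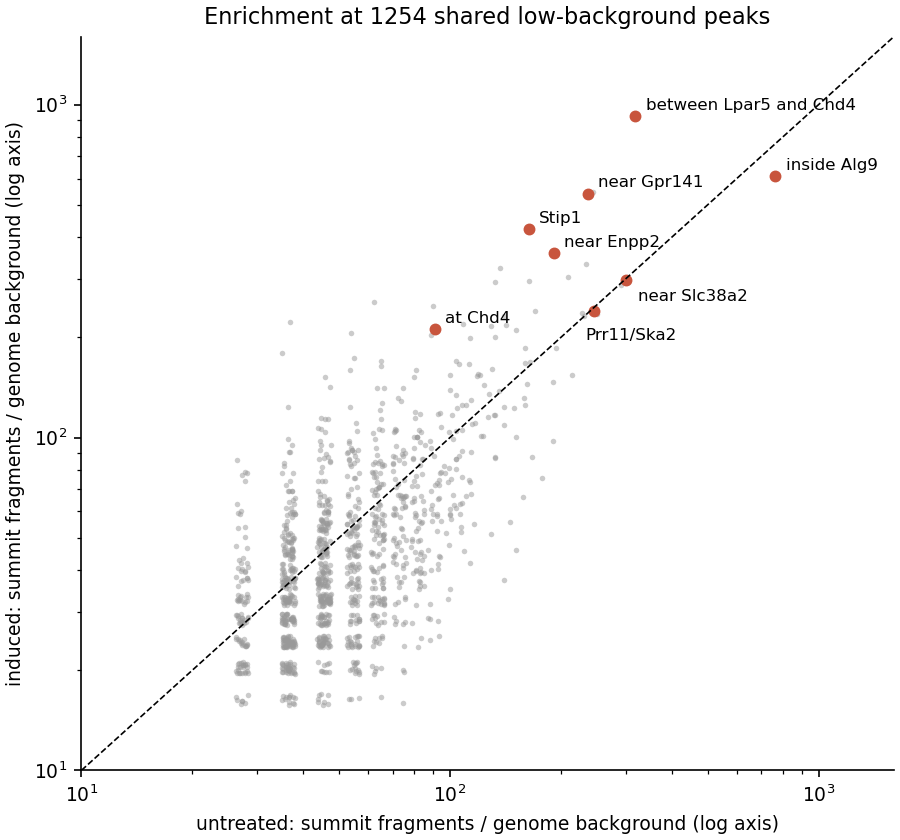
Summit fragments over genome background in the untreated (x axis) and induced (y axis) libraries at 1254 shared peaks, both axes logarithmic, with named sites in red and equality dashed. Points are shifted slightly at random to show overlapping whole numbers; the site between Lpar5 and Chd4 has a ratio of 2.89 and the site inside Alg9 one of 0.797.

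Peaks within 1 kb of a gene end made up 22.3% of the untreated list (20.9 to 23.8) and 21.3% of the induced list (20.4 to 22.2). Shuffled peaks gave 3.08% and 3.04%. A further 34.5% and 32.0% lay inside genes away from their ends, and 42.1% and 46.0% between genes. In all 816 genes had a gene-end peak in the untreated library and 1846 in the induced one. Without genes that had an IgG peak, 525 were shared, where independent lists would share 68.6. Those in the induced list alone numbered 1320, and those in the untreated list alone 288.

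Genes with a gene-end peak in the induced list alone were led by St13 and Xpnpep3, which share a peak of 33 fragments on chromosome 15 (81399588 to 81400279). St13 encodes an Hsp70-interacting cochaperone. Cdca2 and Kctd9 shared another of 33 fragments, Cep57l1 and the stress gene Sesn1 one of 19, and Atf1, encoding a CREB family factor, had 21. Raly and Cops4 had 19 and 18. Sesn1 also had an untreated peak of 15 fragments inside it (41822248 to 41823351 on chromosome 10), which overlapped an induced one of 77. At equal enrichment the St13 peak would have held 14.7 fragments in the untreated library and the Cops4 peak 8.03. Most of the other genes gave less room for a difference. The median induced-only gene held 7 fragments, or 3.12 expected in the untreated library, and 37 of the 1320 had a chance under 0.01 of falling below the lowest called number. By the same measure 99 of the 288 untreated-only genes had a chance under 0.01. The measure takes the fragments of a called peak as the true level and ignores the local background. Genes chosen for a call in their own list alone favour that list, so the expected numbers can be too high. Genes that owe their place to the window, such as Bbs7, were not set apart. Neither the 37 nor the 99 therefore counts genes whose occupancy changed. The median gene of the 288 held 4 fragments, or 8.96 expected in the induced library, where the lowest called number was 4. Peaks of the induced list alone outside gene ends were led by one inside Aspscr1 (chromosome 11, 120682433 to 120683003) with 42 fragments, and those of the untreated list alone by one inside Serpinf1 (chromosome 11, 75419281 to 75419707) with 15, where 33.6 would have been expected in the induced library.

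Genes of the untreated list alone were led by the ubiquitin ligase gene Ubr4 with 12 fragments at 139380366 to 139380643 on chromosome 4. The peak would have held 26.9 fragments in the induced library at equal enrichment, and the nearest induced summit was 53376 bp from the gene. Btg1 came next, with an untreated peak of 10 fragments at its lower end (96616450 to 96617090 on chromosome 10) and an induced peak towards its other end (96621659 to 96621910), 1118 bp from it. At equal enrichment the untreated peak would have held 22.4 fragments in the induced library. Bbs7, with 8 fragments, owed its place to the window, as its untreated peak overlapped an induced one whose summit lay 1016 bp from the gene and which also served Ccna2. Map2k7 and Ovca2 came after these with 7 fragments each.

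Among gene lists fixed in advance, several exceeded random lists in the induced library. Of 42 proteasome genes 13 had a gene-end peak, led by Psmd5 with 16 fragments and Psmd12 with 12, above all 10000 random lists. Histone genes stood at 18 of 71 (percentile 100), fatty acid oxidation genes at 7 of 22, among them Acaa2 and Acsl1 (99.9), and housekeeping genes at 8 of 28, among them Gapdh and Rpl13a (99.9). Cytosolic ribosomal protein genes stood at 15 of 83 (99.7), NuRD genes at 4 of 15 (98.3), with Chd4, Gatad2a, Mbd3 and Mta2, and cell cycle genes, with E2f3 and Pcna, at 6 of 35 (95.1). The NuRD count only equalled the upper bound of random lists, 4, and includes the known target Chd4. Cell cycle genes lay below their bound of 6.025. With a window of 500 bp the induced library kept 2 NuRD genes. Chd4 was not among them, as its induced summit lay 687 bp from the gene. Oxidative phosphorylation genes, with Ndufv1, were at 8 of 87 (62.6) and Zfp genes at 31 of 397 (32.8). Histone genes lie close together, so that 1 peak can serve several, as at H2ac6 and H2bc4. The lists also share members, as Rpl13a and Rplp0 are in both the housekeeping and the ribosomal protein list. Random lists draw on all coding genes, silent ones included, and the housekeeping list was the comparator for open chromatin. It stood at 28.6% (15.3 to 47.1) in the induced library. Proteasome genes at 31.0% (19.1 to 46.0), fatty acid oxidation genes at 31.8% (16.4 to 52.7) and histone genes at 25.4% (16.7 to 36.6) were not set apart from it. In the untreated library 3 proteasome, 6 histone, 1 fatty acid oxidation and 4 housekeeping genes were occupied, at percentiles of 86.6, 96.7, 61.4 and 98.8. Ribosomal protein and NuRD genes numbered 3 and 2 there, at percentiles of 50.7 and 93.8, and cell cycle genes 4, equal to the upper bound of random lists. At a −log10 q of at least 5 the induced library kept 5 histone genes (percentile 85.3), 3 fatty acid oxidation genes (95.6) and 8 ribosomal protein genes (98.0). Proteasome genes numbered 9 there and 0 in the untreated library. In the induced library 4 NuRD genes (99.85), 6 cell cycle genes (99.77) and 5 housekeeping genes (99.62) were kept at this setting. The difference between the libraries in these lists was not tested, and depth alone raises the induced counts.

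Adipogenic and brown thermogenic genes did not exceed random lists in the induced library. Of 45 adipogenic and lipid storage genes 4 were occupied in each library, at percentiles of 94.1 in the untreated and 56.2 in the induced one. At a −log10 q of at least 5 the induced library kept 4 (percentile 91.0) and the untreated one 1 (78.3). Cebpa, a transcription factor gene of adipogenesis, held 6 untreated and 22 induced fragments, a ratio of 1.64 (0.644 to 4.93), and Dgat2 and Fasn had gene-end peaks in the induced list only. Cebpd and Klf5, named after their values had been seen, had them in the untreated list only, with 4 and 3 fragments. Of 30 brown thermogenic genes only Esrra was occupied, in the induced library with 6 fragments (percentile 17.4). The m6A list had 4 of 24 members occupied in the induced library, Hnrnpc, Alkbh5, Fto and Cbll1 (percentile 90.8), and prostaglandin and cAMP signalling had 3 of 34, Atf1, Prkaca and Ep300 (56.2). Neither exceeded random lists, and each kept 1 member at a −log10 q of at least 5. The untreated library had 0 of both, but Prkaca, Ep300, Alkbh5 and Cbll1 would have held only 1.79 to 2.68 fragments there at equal enrichment, below the lowest called number of 3. Hnrnpc and Fto would have held 6.70 each and Atf1 9.37, above it. The bound of 3 applies to sites at the genome background, as at Atf1. The induced peaks at Hnrnpc and Fto held 15 fragments each at folds of only 5.31 and 4.26, over raised local backgrounds. More fragments are needed for a call there, so whether depth hid them in the untreated library was not settled. Of 19 preadipocyte markers only Col1a1 was occupied, in the untreated library. Markers of other cell types had 0 of 28 in both, tissue-restricted genes 2 of 28 in the untreated and 0 in the induced, and olfactory receptors 2 and 1 of 1110.

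**Figure D3:**
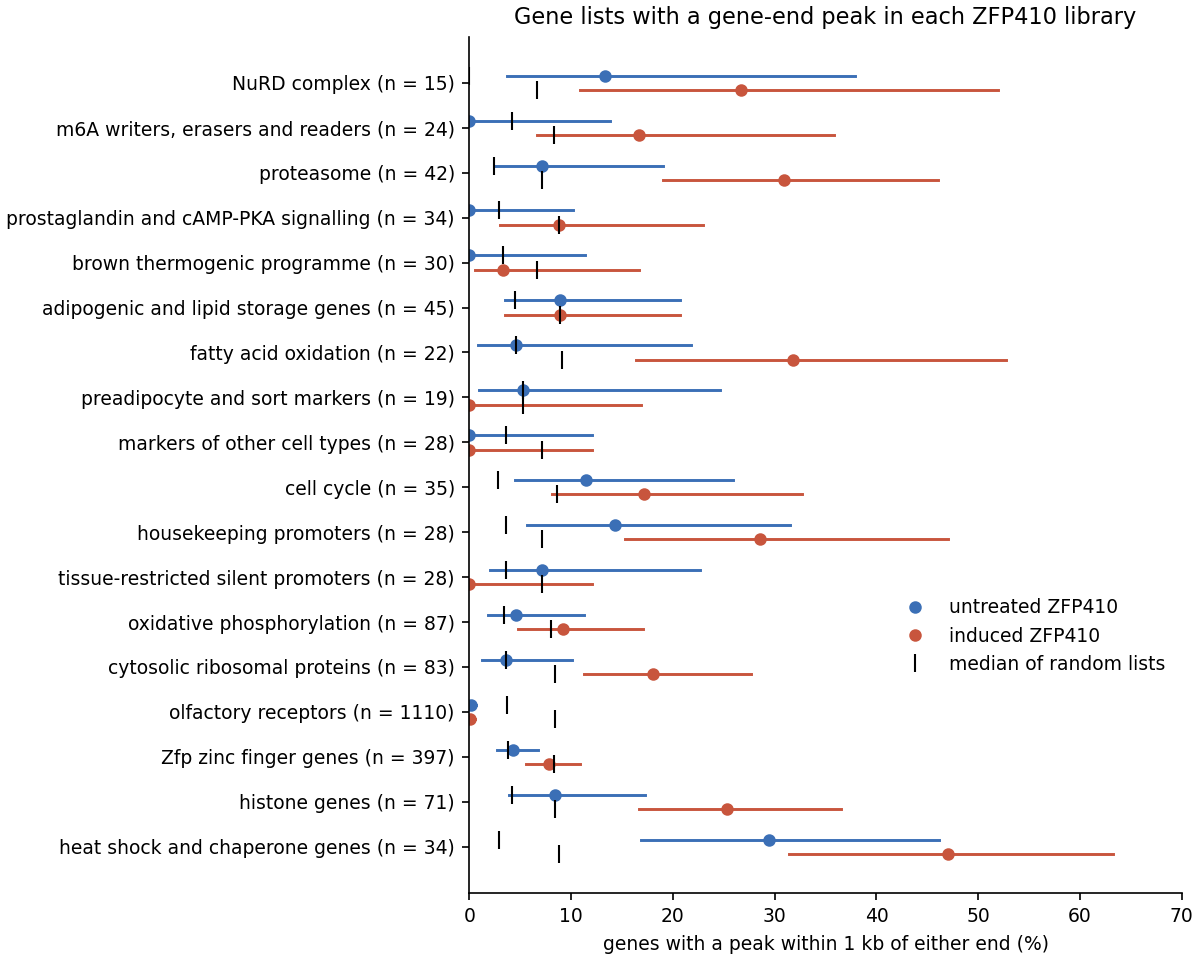
Share of each gene list (%) with a peak within 1 kb of either gene end in the untreated (blue) and induced (red) ZFP410 libraries, with 95% Wilson intervals; black ticks mark the median of random lists of equal size, and the heat shock list was chosen after the strongest peaks had been seen. The proteasome list reached 31.0% in the induced library and olfactory receptors 0.0901%.

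IgG, the background of the assay, gave few peaks at gene ends. The 3 of highest fold were on an unplaced contig, at 72491290 to 72491662 on chromosome 10 and at 3029326 to 3033250 on chromosome 9, with 117, 79 and 152 fragments over high local backgrounds of 4.05, 2.56 and 7.99. Gene ends held 1.67% of IgG peaks (8 of 480, 0.847 to 3.25), against 2.94% of shuffled ones, and 23.3% lay inside genes away from their ends. IgG peaks overlapped 2.24% of untreated peaks (73, 1.79 to 2.81) and 2.27% of induced ones (170, 1.96 to 2.64). After shuffling the shares were 0.0121% and 0.0127%, so the overlap was small but far above shuffled positions. Seen from the IgG list, 43 of its peaks (8.96%) overlapped an untreated and 130 (27.1%) an induced ZFP410 peak, against 0.0834% and 0.203% after shuffling. Among peaks at the genome background 1 of 2553 untreated and 4 of 5226 induced peaks overlapped IgG. The low IgG depth limits what this can show, since the median untreated peak would hold 0.570 fragments there. Of the 21 low-background untreated peaks that would hold at least 3, 1 overlapped an IgG peak, and of the 47 such induced peaks 0 did.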

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

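The settings tried before the data were examined moved sizes more than order: in each of them the induced list held more peaks than the untreated one and the untreated one more than IgG. The added settings and the choice of sites for the enrichment ratio were chosen after the data had been seen. At a −log10 q of at least 5 the lists held 899, 3635 and 100 peaks (untreated, induced, IgG), and at a fold of at least 5 they held 1423, 4824 and 144. With summits of at least 100 times the genome background 168 untreated, 180 induced and 283 IgG peaks were left, an order other than that of the lists (at 50 times, 938 untreated and 972 induced); a shallower library reaches a given ratio with fewer fragments, so that these counts are not matched for noise. Untreated peaks overlapping an induced one made up 74.5% at the q setting, 67.7% at the fold setting, 27.1% where 50% of both peaks had to overlap, 32.8% for summits within 100 bp and 51.0% for peaks within 500 bp. In the same order induced peaks overlapping an untreated one made up 18.4%, 19.7%, 11.8%, 14.3% and 22.4%. Untreated peaks overlapping IgG made up 6.01% at the q setting, 1.12% at the fold setting, 1.52% on placed chromosomes, 0.676% with 50% of both peaks and 0.768% by summits. Induced peaks overlapping IgG made up 0.622% at the fold setting, 1.82% on placed chromosomes, 0.896% with 50% of both peaks and 0.856% by summits. The gene-end share of untreated peaks was 20.4% at the q setting, 25.1% at the fold setting, 17.8% with a window of 500 bp and 28.6% with 2.5 kb. That of induced peaks was 22.4% at the fold setting, 17.7% with 500 bp and 26.5% with 2.5 kb, and that of IgG peaks 0% at the fold setting. Genes in the induced list alone fell to 807 at the q setting. Those in the untreated list alone fell to 58 at the q and 125 at the fold setting, and shared genes to 161 and 299. The enrichment ratio was 0.62 on the log2 scale at the 200 induced peaks with most fragments, against −0.29 over all shared peaks; the other 2 choices stayed within the quartiles. In all, 42 alternatives of these results moved. Another 41, those 2 choices included, stayed within the quartiles, the interval or 1.5 times the reported count. For gene lists 25 of 200 alternatives moved, 21 of them at the q setting, among them histone, fatty acid oxidation and ribosomal protein genes in the induced library. Apart from fewer peaks at stricter thresholds, the cause was not tested. Motif settings were not run, as no sequence was used here, and leaving out a replicate was not possible with 1 library per group. Depth limits the IgG and untreated lists most.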

Other observations

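Several tests here were chosen only after related values had been seen, namely those of high-background sequence, of open chromatin, of the strongest sites and of heat shock genes. Heat shock and chaperone genes formed a group that the lists fixed in advance did not hold. Of 34 such genes 10 had a gene-end peak in the untreated library and 16 in the induced one, led by Stip1, Hspa1a, Hspa1b and Dnaja1. The list was written because some of these genes were among the strongest peaks, so the 30 members not seen by then were counted on their own. Of these 6 were occupied in the untreated library and 12 in the induced one, where random lists had medians of 1 and 2. A hypothesis is that ends of heat shock genes may be favoured sites in these cells. Housekeeping genes, also above random lists at 8 of 28 in the induced library, leave open that this is a property of active genes, and no expression was measured. The housekeeping list itself holds the heat shock genes Hsp90ab1 and Hspa8, so the comparison is not independent. Chromosome X held 1.54% of untreated and 3.18% of induced peaks, and chromosome Y 2.92% and 2.38%; IgG had 38 peaks on X (7.92%) and 1 on Y.

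More ZFP410 peaks were called after induction. Depth as the whole cause was argued against, as thinning the induced library to the untreated depth left at least 5100 peaks in each of 100 draws, against 3256. Since the draw ignores the minimum peak width, summits with 8 or more fragments were compared too: 740 on average after thinning against 438. Higher enrichment at the same sites stays open. The ratio was 0.792 at the 200 untreated peaks with most fragments, at or below the bound of 1 set against it, but that choice favours the untreated library, and the reverse choice gave 1.54. A change of ZFP410 binding with differentiation and a difference between 2 single preparations could each produce this, and neither was testable with 1 library per group.

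Few ZFP410 peaks overlapped IgG, though more than after shuffling. The low IgG depth as the whole cause was argued against, as thinning the untreated peaks to that depth left at least 451 callable, against 73 that overlapped. Most of those 451 rest on few fragments, but of the 21 low-background untreated peaks expecting at least 3 fragments there, 1 overlapped IgG. The overlap of untreated peaks may come from sequence of high background, since 79.5% of the 73 had a local background over 10 times the genome background, against 0.911% of the other untreated peaks. For the 170 induced peaks that overlapped IgG the share was 49.4% (42.0 to 56.9), against 1.71% of the others, which leaves the rest of that overlap open. No biological explanation was tested.

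ZFP410 peaks favoured gene ends. In the induced library the ends of ribosomal protein and housekeeping genes were favoured, as open chromatin cut without the antibody would give, but in the untreated one ribosomal protein genes stood at 3 of 83, the median of random lists, while housekeeping genes stood at 4 of 28, where that median was 1. IgG had 8 peaks at gene ends, a share within the shuffled range. By the bound added late the counts went against open chromatin as the whole source. At IgG depth at least 84 untreated gene-end peaks were left in each draw, against 8 IgG peaks. With at least 3 fragments 18 to 45 were left against 4. With at least 4 fragments 4 to 18 were left against 3, too few to decide for the strongest. Only 6 low-background untreated gene-end peaks would hold at least 3 fragments at that depth, and 0 of them overlapped IgG. Most of the 84 thus rest on few fragments, and the draw ignores the minimum peak width. Open chromatin as the whole or a part of the source therefore stays open. The gene-end share was not confined to the strongest sites. Of the 200 induced peaks of highest fold 18.0% (13.3 to 23.9) lay at gene ends, and 21.4% of the rest did. Both were above the 3.04% of shuffled peaks. The bound for this was also added after the shares had been seen, and 200 of 7475 peaks could not make up the share alone. Binding of ZFP410 at these ends through other proteins was not tested.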
